A study of Mus musculus with 7 samples.

How the data were processed

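RNA-seq was run on total RNA of 7 mouse cell cultures in 3 groups. The groups were adult cardiac fibroblasts (CF, n = 3, passage 1 to 2), induced cardiac progenitor cells (iCPC) at low passage (n = 2, passage 1 to 3) and iCPC at high passage (n = 2, passage 8 to 10). Groups and replicate numbers came from the sample titles. Each library came as a table of expected counts and a table of TPM for the same 20325 gene symbols.

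The expected counts were deposited as the authors' RSEM estimates, which share reads that fit several genes among them and need not be whole. The TPM tables were deposited as the authors' values and sum to 1000000 per library. Per the submitters' processing notes, the tools were CASAVA 1.8.2, Bowtie 0.12.9 and RSEM 1.2.3, with the mouse genome build mm9. The annotation, the read length and the use of strand were not given in the sources used here. Without strand, reads of a gene and of an antisense partner cannot be told apart. Reads of near-identical paralogs, such as members of the Serpinb9 and Ifit families, were divided by a model, so single members of such families carry extra uncertainty. Reads from an introduced copy of a factor and from the cell's own gene are counted under the same symbol.

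Expected counts were rounded to whole numbers. The library totals ran from 14085672 to 27096817, and 3 counts, used as the floor for a gene at 0, correspond to 0.108 to 0.223 CPM (counts scaled to a library of 1000000). This floor covers counting error only. Genes were kept with the filterByExpr function of edgeR by group, which left 13458 genes. Libraries were scaled with TMM factors, and CPM values use the scaled library sizes. The main test was the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) on a model with the 3 groups and no other term, fitted to all 7 libraries so that the groups share one estimate of the spread. The contrasts were the mean of both iCPC groups against CF, low passage against CF, high passage against CF, and high against low passage. P-values were adjusted by the Benjamini-Hochberg method over the genes of a contrast, and a gene was called at an adjusted p under 0.05. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of its F value. The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Alternatives chosen afterwards are named as such.

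Before the test was used, it was tested on simulated counts for 13458 genes drawn from these libraries' means, sizes and spread, with 200 genes changed in each of 5 simulations. For iCPC against CF, edgeR recovered 0.896% of genes changed by a log2 value of 1, 18.8% at 2 and 72.7% at 4, and 8.66% of its calls were false. For high against low passage the shares were 0.299%, 1.79% and 47.6%, with 8.38% false calls. DESeq2 made 39.6% and 45.3% false calls in the same simulations for these comparisons. In the list test a simulated list of 30 genes shifted by a log2 value of 1 was called in 5 of 5 simulations, and 0 of 120 unshifted lists were called, in each of these comparisons. In these simulations each gene varied independently of the others, so they cannot show how often the list test calls lists when genes vary together.

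Gene lists numbering 27 were written from textbook knowledge. The reprogramming factors and the sex-linked genes were read gene by gene. The other 25 lists had at least 5 tested members and were tested with camera (limma 3.58.1) on log2 CPM with its preset inter-gene correlation of 0.01, with adjustment over the 25 lists of a contrast. They covered cardiac progenitor regulators, cardiomyocytes, fibroblasts, smooth muscle, endothelium, leukocytes, epicardium, epithelium, skeletal muscle, neural, blood, fat and skeletal cells, and cell cycle, p53, pluripotency, Wnt, LIF/STAT3, interferon, TGF-beta, respiration, glycolysis, cholesterol, imprinted and Hox genes. Some genes stand in more than one list. Genes were also adjusted over the list alone. Medians of a list per library are given on the scale log2(CPM + 0.5) relative to the mean of the 3 CF libraries, which understates changes of weakly expressed genes. List medians of fitted changes are also given with genes at or below the floor set to their bound, 3 counts over the group.

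Genes named in the text follow a rule with 3 parts. The first part takes Mesp1, Tbx5, Gata4, Nkx2-5, Smarcd3 and the sex-linked genes in every library, as values with no fold change. The second part takes the called genes with the largest change (10 in each direction for iCPC against CF and for high against low, 5 in each direction otherwise), with a mean log2 CPM of at least 4, no overlap between replicates, and without unnamed gene models and ribosomal proteins. The third part takes up to 4 members of each list with the smallest p-value in a contrast. A called gene and a list member that this rule selects are not reported here. Since few genes were called, further genes, Chl1 among them, were chosen after their values were seen, and these are named as such.

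Alternatives were RLE and upper-quartile scaling, no filter, a mean of at least 50 counts, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1) for genes with a TPM of at least 1 in 2 libraries and log2(TPM + 1) with no filter, a replicate block, a library set block, only the groups compared, a minimum log2 fold change of 1, each library left out, and both iCPC groups as one. Lists were also tested with an estimated correlation and with fry. The library sets are a pair of runs of consecutive library numbers. Set 1 holds CF 1, low 1 and high 1, and set 2 holds CF 2, CF 3, low 2 and high 2. The first passage number in the column header of the library labelled low passage replicate 2 is 7, while its label gives passage 1 to 3. The library was kept in the group its label gives, and an alternative chosen after seeing the data moves it to the high-passage group. Further alternatives chosen after seeing the data were each library set alone and the removal of all genes of chromosomes 4 and 12.

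Genes were placed on chromosomes by symbol or a unique synonym with the RefSeq table of GRCm38.p6, used for chromosome membership and gene order only, which placed 20137 of 20325 symbols. No coordinates are given because this build differs from mm9. Chromosome medians used 10520 genes with a mean of at least 100 counts. Each iCPC library was set against the mean of the CF libraries and each CF library against the mean of the other CF libraries, and values were centred on the median of the autosomal genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for these steps and the figures.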

Results

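Gene expression was measured by RNA-seq in cultured mouse adult cardiac fibroblasts (CF, n = 3), in induced cardiac progenitor cells (iCPC) at low passage (n = 2) and in iCPC at high passage (n = 2). The series title describes iCPC as cells made by reprogramming mouse fibroblasts with defined factors, so the comparisons ask how iCPC differ from fibroblasts and how passage changes them. Total expected counts were 25432984, 18503667 and 21591495 for CF 1, 2 and 3, 23648226 and 14085672 for low 1 and 2, and 27096817 and 18131161 for high 1 and 2. Low 2, the shallowest library, had 13257 genes above 0 and the other libraries 14889 to 15415. The labels place low 1 and high 1 in iCPC batch 1, low 2 in batch 4 and high 2 in batch 3. The labels give CF 2 as female and CF 3 as male. For the other replicates they do not say whether animals or inductions were separate, so p-values measure only the spread between these samples. The column headers name passage 1 for low 1, passage 7 for low 2 and high 1, and passage 8 for high 2, whereas the labels give passage 1 to 3 at low and 8 to 10 at high passage. The library labelled low 2 thus carries the same header passage as high 1. This limits every result that rests on its place in the low-passage group. Only the first passage number in each header was read, so a further number in a header is not covered.

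Libraries resembled each other by library set as well as by group. Across genes, CF 2 and CF 3 were the closest pair (r = 0.965), and low 1 was closest to high 1 of the same batch (r = 0.945). CF 1 was closest to low 1 (r = 0.938), a library of its own set. Low 2 was closest to high 2 of its set (r = 0.885), while high 2 was closest to high 1 of the other set (r = 0.911). No pair of libraries agreed within sampling noise.

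The cardiac transcription factors were read first. Mesp1, a regulator of early cardiac mesoderm, was at 0 counts in all 7 libraries, which allows up to 0.223 CPM in the shallowest. Nkx2-5 was at 7.04 CPM in high 2 and at or below 0.306 CPM in the other libraries. Gata4 was at 119 to 159 CPM in CF and 123 to 214 CPM in iCPC. Tbx5 was at 5.27 to 13.6 CPM in CF, 22.5 to 27.6 CPM in low 1, high 1 and high 2, and 0 counts in low 2. Smarcd3, a subunit of a cardiac chromatin remodelling complex, was at 21.1 to 39.5 CPM in CF and 31.7 to 82.5 CPM in iCPC. Of the 17 tested genes for cardiomyocyte contraction and ion handling, 8 were higher and 9 lower in iCPC, and the list did not pass the test (camera adjusted p = 0.948). Tnnt2, cardiac troponin T, varied among iCPC libraries from 0.717 CPM in high 1 to 205 CPM in low 2, with 3.29 to 13.3 CPM in CF.

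Transcripts of macrophages and other leukocytes fell in iCPC against CF. All 21 tested members were lower, 18 of them called when adjusted over the list alone and 0 over all genes (camera adjusted p = 8.44e-19, and adjusted p = 0.586 with an estimated correlation). The median log2 change was -8.86, or -7.61 with genes near 0 at their bound. Laptm5, a lysosomal protein of haematopoietic cells, was at 34.3, 230 and 26.3 CPM in CF 1, 2 and 3 and at or below 0.078 CPM in every iCPC library. The iCPC values lie under the floor of 3 counts (0.108 to 0.223 CPM). Cd53, a leukocyte tetraspanin, changed by a log2 value of -7.61 ± 0.93 (SE), and Mrc1, the macrophage mannose receptor, by -7.58 ± 1.01 (SE), each with an edgeR adjusted p above 0.05 over all genes. The CF libraries themselves differed on this list, with a median of 2.04 in CF 2 and -1.74 in CF 3 relative to the CF mean. Within library sets 1 and 2 the median difference between iCPC and CF was -4.48 and -4.32 on the scale log2(CPM + 0.5).

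Fibroblast matrix genes also fell in iCPC as a group. Of 28 tested members 18 were lower, 2 of them called when adjusted over the list alone (median log2 change -0.69, camera adjusted p = 0.00105, adjusted p = 0.586 with an estimated correlation). The medians within sets 1 and 2 were -0.82 and -0.69, and with set 2 alone the list's adjusted p was 0.0975. Postn, the matrix protein periostin, was at 49.5, 587 and 334 CPM in CF and 0.108 to 3.97 CPM in iCPC. Mfap5, a microfibril protein, was at 48.0 to 68.9 CPM in CF, 27.6 and 28.7 CPM in low-passage iCPC and 3.52 and 8.86 CPM in high-passage iCPC. Col5a2, a fibrillar collagen chain, had a log2 change of -1.40 ± 0.40 (SE), and Fbn1, fibrillin, of -1.16 ± 0.35 (SE). Targets of TGF-beta, a list that shares Postn, fell with 16 of 20 members lower (median -0.68, camera adjusted p = 0.0104, adjusted p = 0.586 with an estimated correlation). The TGF-beta call was lost without low 1 (adjusted p = 0.233), without high 2 (0.0721) and with set 2 alone (0.0802), and the medians within sets were -0.64 and -0.67.

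Endothelial markers fell, with all 15 tested members lower and none called when adjusted over the list alone (median log2 change -2.69, camera adjusted p = 0.00198, adjusted p = 0.586 with an estimated correlation). Vwf, von Willebrand factor, was at 4.13, 11.2 and 4.53 CPM in CF and 0.0740 to 2.14 CPM in iCPC, and Kdr, a VEGF receptor, was at 0.390 to 2.63 CPM in CF and 0.108 to 0.213 CPM in iCPC. CF 1 held more of these transcripts than the other CF libraries, with a median of 1.71 against -0.68 in CF 2 and -1.10 in CF 3. The medians within sets were -2.56 and -0.97, and the call was lost without CF 1 (adjusted p = 0.0640) and without low 2 (0.0682).

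Genes induced by interferon fell, with 23 of 24 tested members lower and 4 called when adjusted over the list alone (median log2 change -1.75, camera adjusted p = 5.35e-07, adjusted p = 0.646 with an estimated correlation). Ifit3 was at 183, 507 and 672 CPM in CF, 273 CPM in low 1, lower in low 2, and 4.55 and 14.7 CPM in high-passage iCPC. Isg15, a ubiquitin-like protein, had a log2 change of -3.69 ± 1.00 (SE), Oas1a, an RNA-sensing enzyme, of -5.24 ± 1.33 (SE) and Irf7, a transcription factor of the same response, of -2.62 ± 0.72 (SE). Within set 1 the median was -0.13, with 0.81 for low 1 and -1.09 for high 1 against CF 1, and the list's test turned to the opposite direction with an adjusted p of 0.883. Within set 2 the median was -2.73.

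Glycolysis genes fell, with 16 of 19 tested members lower, 4 lower and 1 higher called when adjusted over the list alone (median log2 change -0.92, camera adjusted p = 0.00107, adjusted p = 0.646 with an estimated correlation). Slc16a3, a lactate exporter, had a log2 change of -4.34 ± 0.77 (SE), Eno1, an enolase on chromosome 4, of -1.83 ± 0.35 (SE) and Pfkl, a phosphofructokinase, of -1.15 ± 0.30 (SE). Eno2, the neuronal enolase, went the other way at 1.41 ± 0.40 (SE). The medians within sets were -0.14 and -0.92, and the call was lost in set 1 alone (adjusted p = 0.629).

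Cell cycle genes rose in iCPC, with all 35 tested members higher and none called when adjusted over the list alone (median log2 change 1.41, camera adjusted p = 1.07e-09, adjusted p = 0.646 with an estimated correlation). Mcm7, a replication helicase subunit, was at 15.7 to 24.9 CPM in CF and 36.2 to 97.2 CPM in iCPC. Foxm1, a transcription factor of dividing cells, had a log2 change of 1.64 ± 0.45 (SE), and Aurka and Plk1, mitotic kinases, of 1.93 ± 0.58 and 1.60 ± 0.59 (SE). Low 2 was the highest library, with a list median of 2.36 against 0.60 in low 1, 1.57 in high 1 and 0.16 in high 2, and CF 1 was at 0.51. The medians within sets were 0.58 and 1.64. Some other splits of the libraries, which mix iCPC with CF, gave this list a smaller adjusted p than iCPC against CF, as given below.

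Oxidative phosphorylation genes rose by a smaller amount, with 36 of 39 tested members higher (median log2 change 0.37, camera adjusted p = 0.000453, adjusted p = 0.667 with an estimated correlation). Ndufa4, a respiratory chain subunit, was at 39.4 to 99.8 CPM in CF and 88.8 to 211 CPM in iCPC, and Cox7c, a cytochrome oxidase subunit, had a log2 change of 0.82 ± 0.31 (SE). The call was lost without low 2 (adjusted p = 0.172) and in set 1 alone (0.654), where the median was 0.03 against 0.61 in set 2. Cholesterol synthesis genes rose, with 18 of 20 higher (median 0.53, camera adjusted p = 0.00899, adjusted p = 0.667 with an estimated correlation). Idi1 and Fdft1, enzymes of the isoprenoid and squalene steps, were at 21.1 and 35.0 CPM in low 1, below every CF library, and at 77.3 CPM or more in the other iCPC libraries. This call was lost without CF 1 (0.293), low 2 (0.475) or high 1 (0.0524), in set 1 alone (0.0849) and with low 2 grouped by its header (0.330), with medians of 0.59 in each set.

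The remaining 15 lists did not pass in iCPC against CF besides the cardiomyocyte list. Camera adjusted p-values were 0.125 for cardiac progenitor and mesoderm regulators, 0.127 for neural and neural crest genes, 0.257 for smooth muscle, 0.334 for epithelium and for LIF/STAT3 targets, 0.349 for blood and 0.374 for Wnt targets. They were 0.386 for epicardium, 0.435 for skeletal muscle and for cartilage and bone, 0.466 for p53 targets, 0.536 for fat, 0.711 for Hox genes and 0.890 for imprinted and for pluripotency genes. Among progenitor regulators Wnt5a, a secreted Wnt ligand, was at 22.6 to 50.5 CPM in CF and 2.68 to 13.0 CPM in iCPC. Aldh1a2, the retinoic acid enzyme of the epicardium, was at 12.3 to 60.7 CPM in CF and 0.213 to 3.07 CPM in iCPC, and Tbx18, an epicardial transcription factor, at 41.4 to 94.7 and 19.7 to 34.5 CPM. The epicardial list split by library set, with a median difference between iCPC and CF of -3.14 within set 1 and 2.21 within set 2, so its pooled median of 0.59 describes neither. Among iCPC the sets also separate batch 1 from the other batches.

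**Figure D1:**
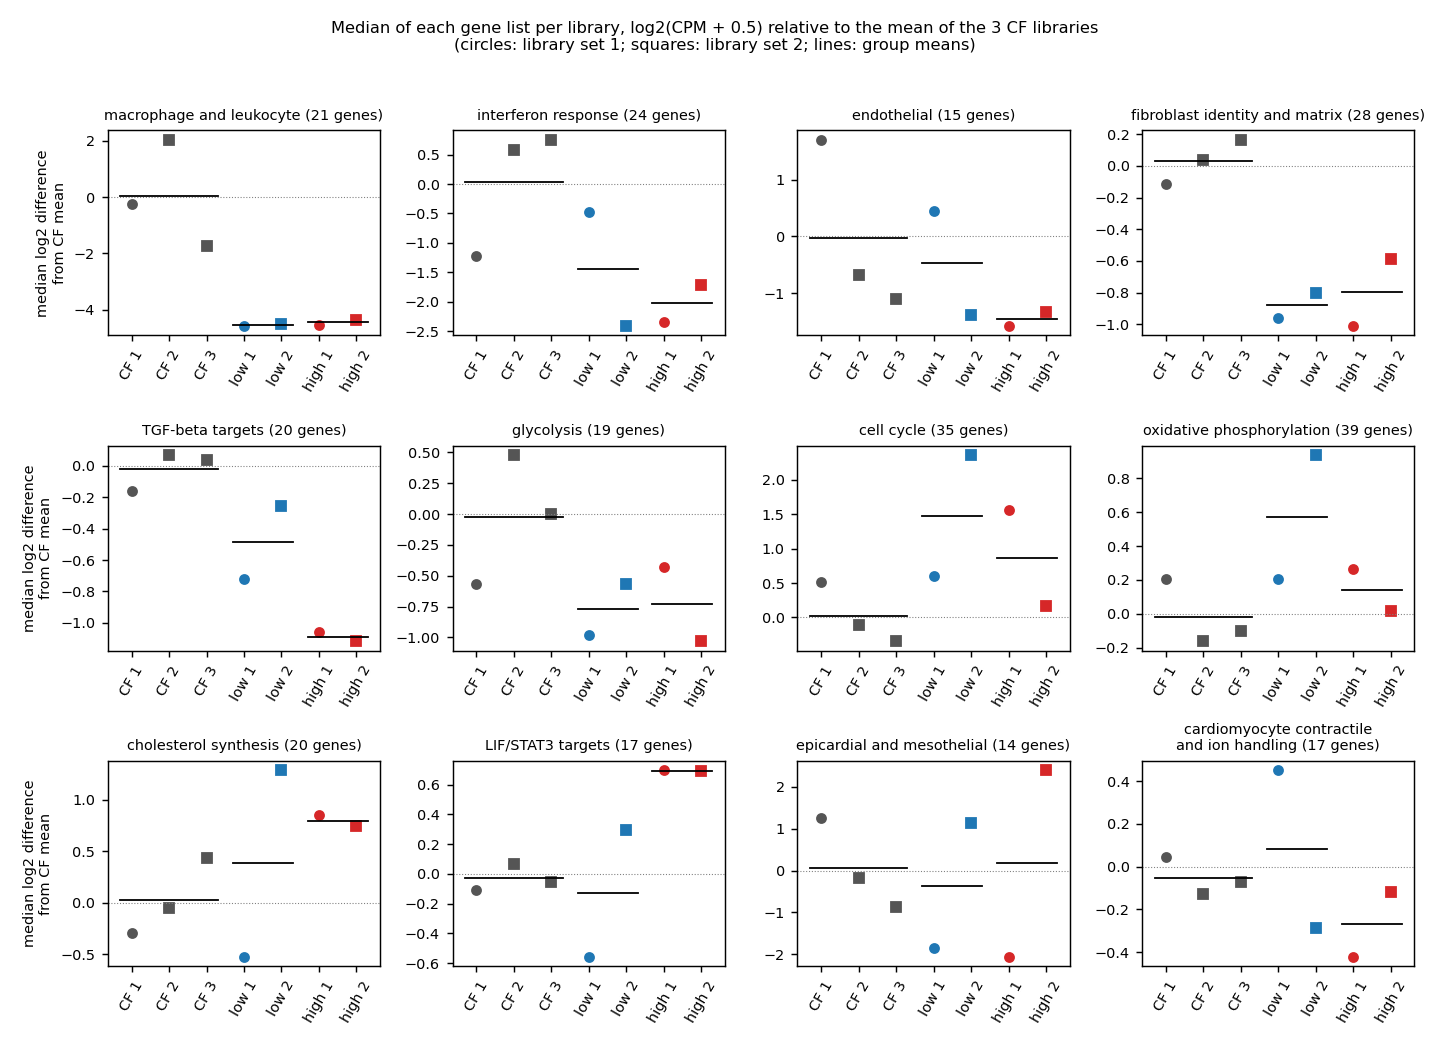
Median of 12 gene lists in each library (vertical axis, log2(CPM + 0.5) relative to the mean of the 3 CF libraries), for CF in grey, low-passage iCPC in blue and high-passage iCPC in red. Circles are library set 1, squares set 2 and lines group means, and the leukocyte medians of the 4 iCPC libraries lie between -4.58 and -4.37.

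Gene by gene, iCPC against CF gave 0 calls with edgeR, with 1762 of 13458 genes at an unadjusted p under 0.05. Chance would give 673 if all libraries varied independently, which their resemblance by set and batch goes against. Other splits of the libraries, described below, gave 73 to 2155 such genes. limma-voom also gave 0 and DESeq2 774, of which 117 were higher and 657 lower. Leaving out CF 1 gave 72 calls, and leaving out CF 3 gave 12. The libraries of iCPC and CF did not overlap for 1688 genes, or 12.5%, where chance would give 5.71% if all libraries could be exchanged. Changes measured in set 1 and in set 2, which share no library, hardly correlated across genes (r = 0.0508 over 7746 genes), and 53.2% had the same sign. Among genes chosen after their values were seen, Serpinb9b, a serine protease inhibitor, had the smallest p, with a log2 change of -3.69 ± 0.30 (SE) and an edgeR adjusted p of 0.0589. Col8a1, a short-chain collagen, was at 782 to 1075 CPM in CF and 97.9 to 185 CPM in iCPC (log2 change -2.70 ± 0.28, SE, edgeR adjusted p = 0.0746). Adamts5, a proteoglycan-cleaving protease, was at 360 to 1347 CPM in CF and 72.5 to 148 CPM in iCPC. Kitl, the ligand of the receptor Kit, was at 51.5 to 133 CPM in CF and 7.36 to 39.6 CPM in iCPC.

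Low-passage iCPC against CF gave 6 called lists of 25. Endothelial genes, TGF-beta targets and cholesterol synthesis, called for both iCPC groups together, did not pass here (camera adjusted p = 0.0877, 0.0877 and 0.554). The leukocyte list fell with all 21 members lower (median log2 change -8.83, or -6.91 with genes near 0 at their bound, camera adjusted p = 3.97e-17). Cell cycle genes rose with 35 of 35 higher (mean 1.67, 1.73e-11), and oxidative phosphorylation with 38 of 39 higher (median 0.61, 3.82e-07). Interferon genes fell with 23 of 24 lower (median -1.38, 0.000199), fibroblast matrix with 22 of 28 lower (median -0.80, 0.000406) and glycolysis with 17 of 19 lower (median -0.84, 0.00338). With an estimated correlation the adjusted p was 0.672 for leukocytes and fibroblast matrix, 0.703 for interferon and 0.695 for cell cycle, oxidative phosphorylation and glycolysis. Without low 2 the calls of oxidative phosphorylation (adjusted p = 0.174) and interferon (0.757) were lost, and without low 1 those of fibroblast matrix (0.0511) and glycolysis (0.276). With low 2 grouped by its header those of oxidative phosphorylation (0.137) and interferon (0.630) were lost. In set 1, low 1 minus CF 1 had medians of -4.28 for leukocytes, 0.07 for cell cycle, -0.04 for oxidative phosphorylation, 0.81 for interferon, -0.91 for fibroblast matrix and -0.30 for glycolysis. No gene passed over all genes with edgeR (0 calls), limma-voom gave 0 and DESeq2 426, of which 39 were higher and 387 lower. With edgeR 1500 genes had an unadjusted p under 0.05, where independent libraries with no change would give 673.

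High-passage iCPC against CF gave 3 called genes with edgeR, 1 higher and 2 lower, among them Chl1 and Serpinb9b. Chl1 lies below the expression minimum of the rule for named genes, and was named after its values were seen. Chl1, a neural cell adhesion molecule, rose from 1.11 ± 0.44 CPM in CF (SD, n = 3) to 213 ± 34.0 CPM (SD, n = 2), a log2 change of 7.58 ± 0.46 (SE, edgeR adjusted p = 0.00700). Serpinb9b fell from 176 ± 40.4 to 6.94 ± 2.40 CPM (log2 change -4.67 ± 0.43, SE, edgeR adjusted p = 0.0408). All 5 libraries showed the direction of Chl1 and of Serpinb9b without overlap, and 1420 genes had an unadjusted p under 0.05. Over its 21 alternatives the adjusted p ran from 1.56e-53 to 0.212 for Chl1 and from 1.94e-27 to 0.410 for Serpinb9b. Leaving out CF 1, CF 2 or CF 3 gave 4, 1 and 2 called genes, and of the 3 genes called above only Chl1 stayed called in each of these fits. Leaving out high 1 or high 2 leaves 1 library in that group, and no call was kept. The log2 changes were then 7.73 and 7.41 for Chl1 and -4.35 and -5.07 for Serpinb9b. With low 2 grouped by its header 2 genes were called and 0 of these 3, with adjusted p-values of 0.212 for Chl1 and 0.187 for Serpinb9b. Serpinb9b also lost its call without any one of the 7 libraries (0.0579 to 0.410). A replicate block ended the calls of Chl1 (edgeR adjusted p = 0.0786) and Serpinb9b (0.0828), and with only the groups compared Serpinb9b was not called (0.117). DESeq2 called 535 genes, 109 higher and 426 lower.

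The gene lists called in high-passage iCPC against CF numbered 10 of 25. Leukocyte genes fell with 20 of 21 lower (median log2 change -9.41, or -7.17 with genes near 0 at their bound, camera adjusted p = 9.23e-18), interferon genes with 23 of 24 lower (median -2.24, 2.05e-07) and endothelial genes with 15 of 15 lower (median -3.35, 0.000323). Glycolysis (median -0.72, 0.00401), TGF-beta targets (median -0.76, 0.00701), fibroblast matrix (median -0.62, 0.0114) and smooth muscle genes (median -1.26, 0.0407) fell. Cell cycle genes rose with 33 of 35 higher (median 1.03, 3.62e-05), cholesterol synthesis with 19 of 20 higher (median 0.68, 9.62e-05) and LIF/STAT3 targets with 14 of 17 higher (median 0.61, 0.00362). With an estimated correlation the adjusted p was 0.588 for cell cycle and 0.494 for each of the other 9 lists. In set 1, high 1 minus CF 1 had medians of -4.58 for leukocytes, -1.09 for interferon, -3.20 for endothelium, 0.10 for glycolysis, -0.66 for TGF-beta targets, -0.91 for fibroblast matrix, -1.79 for smooth muscle, 1.04 for cell cycle, 1.26 for cholesterol synthesis and 0.63 for LIF/STAT3 targets. Without CF 1 the calls of fibroblast matrix (adjusted p = 0.0951) and smooth muscle (0.568) were lost, without high 1 those of cell cycle (0.580), fibroblast matrix (0.363) and smooth muscle (0.199), and without high 2 those of glycolysis (0.338) and TGF-beta targets (0.144). With low 2 grouped by its header that of TGF-beta targets (0.0874) was lost.

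The changes of low- and high-passage iCPC were both taken against the same CF libraries, which adds agreement by itself. Across 7746 genes they correlated at r = 0.578, where simulated groups with no change gave 0.394 ± 0.0128 (SD of 30 simulations). The covariance was 0.281 against 0.125 simulated, a difference of 0.156. The same sign was found for 68.3% of genes, against 63.1% simulated. With low and high passage each taken against CF libraries that the other did not use, a test chosen after the result was seen, r was 0.0116 to 0.112 where CF 1 stood on one side. It was 0.626 and 0.707 between CF 2 and CF 3, which are of the same set, so the agreement depended on which controls were used. The simulation also leaves out what low and high libraries of the same number share (r = 0.284 between their deviations), which follows the library sets and adds agreement as well.

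High against low passage gave 1 called gene with edgeR. Chl1 rose from 0.361 ± 0.015 CPM (SD, n = 2) in the libraries labelled low passage to 213 ± 34.0 CPM (SD, n = 2), a log2 change of 9.19 ± 0.60 (SE, edgeR adjusted p = 0.0122). Its change was positive under all 21 alternatives, with adjusted p-values from 1.10e-45 to 0.980, and the call was lost without CF 1 (0.0517), low 1 (0.140), low 2 (0.140) or high 2 (0.119), with a library set block (0.0664), with only the groups compared (0.0705), with limma-voom (0.102), on log2(TPM + 0.1) (0.0828) and with the library labelled low 2 grouped by its header (0.980). Leaving out high 1 gave 2 called genes. A replicate block also ended the call of Chl1 (edgeR adjusted p = 0.139). DESeq2 called 70 genes, 51 higher and 19 lower, and limma-voom 0. With edgeR 638 genes had an unadjusted p under 0.05, where independent libraries with no change would give 673. The share of genes whose libraries did not overlap, 28.8%, was below the 33.3% of chance for libraries that can be exchanged. The change from low 1 to high 1 and that from low 2 to high 2, which share no library, correlated at r = 0.153 across genes.

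Of the gene lists 6 of 25 were called between the passage groups. LIF/STAT3 targets rose with 16 of 17 members higher (median log2 change 0.74, camera adjusted p = 9.15e-05, adjusted p = 0.727 with an estimated correlation). Stat3 was at 208 and 210 CPM at low and 428 and 503 CPM at high passage, and Socs3, a feedback inhibitor, at 23.7 and 144 CPM at low and 261 and 338 CPM at high passage. The median was 1.36 from low 1 to high 1 and 0.25 from low 2 to high 2, and the call was lost without low 1 (0.434). Cholesterol synthesis genes rose with 14 of 20 higher (median 0.41, camera adjusted p = 0.00182, adjusted p = 0.727 with an estimated correlation). Their median was 1.45 from low 1 to high 1 and -0.46 from low 2 to high 2, and the call was lost without low 1 (0.566, in the opposite direction) and without high 1 (0.0871). Epithelial genes rose with 9 of 9 higher (median 1.45, camera adjusted p = 0.0347, adjusted p = 0.727 with an estimated correlation). Krt7, a keratin, was at 0.506 and 0.743 CPM at low passage, 0.789 CPM in high 1 and 15.5 CPM in high 2. The median was 0.18 from low 1 to high 1 and 1.58 from low 2 to high 2, and the call was lost without low 1 (0.446), without high 2 (0.949, in the opposite direction) and with low 2 grouped by its header (0.0867). Pluripotency genes rose with 5 of 5 tested members higher (median 1.40, camera adjusted p = 0.0190, adjusted p = 0.727 with an estimated correlation). The members were Klf2, Klf4, Dnmt3b, Dnmt3l and Nanog. Klf2 and Klf4 also act in differentiated cells, and Klf2 was at 3.64 and 6.19 CPM at low and 21.5 and 26.4 CPM at high passage, while Nanog was below 1 CPM in every library. The medians of the pairs were 0.61 and 1.23, and the call was lost without low 1 (0.308), low 2 (0.123) or high 2 (0.0874) and with low 2 grouped by its header (0.519).

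Oxidative phosphorylation genes fell from low to high passage with 34 of 39 lower (median log2 change -0.52, camera adjusted p = 9.15e-05, adjusted p = 0.727 with an estimated correlation). Uqcrq, a subunit of respiratory complex III, was at 92.8 and 187 CPM at low and 78.4 and 50.3 CPM at high passage. The median was 0.06 from low 1 to high 1 and -1.04 from low 2 to high 2, and the call was lost without low 2 (0.854). Cell cycle genes fell with 31 of 35 lower (median -0.63, camera adjusted p = 0.00301, adjusted p = 0.768 with an estimated correlation). Cdc20, which activates the anaphase-promoting complex, was at 5.33 CPM in low 1, 40.4 CPM in low 2, 8.29 CPM in high 1 and 4.16 CPM in high 2. The median was 0.90 from low 1 to high 1 and -2.35 from low 2 to high 2, and the direction turned without low 2 (0.128) and without high 2 (0.615). With low 2 grouped by its header, which leaves low 1 alone at low passage, the oxidative phosphorylation and cell cycle lists turned to the opposite direction. The other 19 lists did not pass between the passage groups, with adjusted p-values from 0.0540 for smooth muscle to 0.968 for cartilage and bone.

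**Figure D2:**
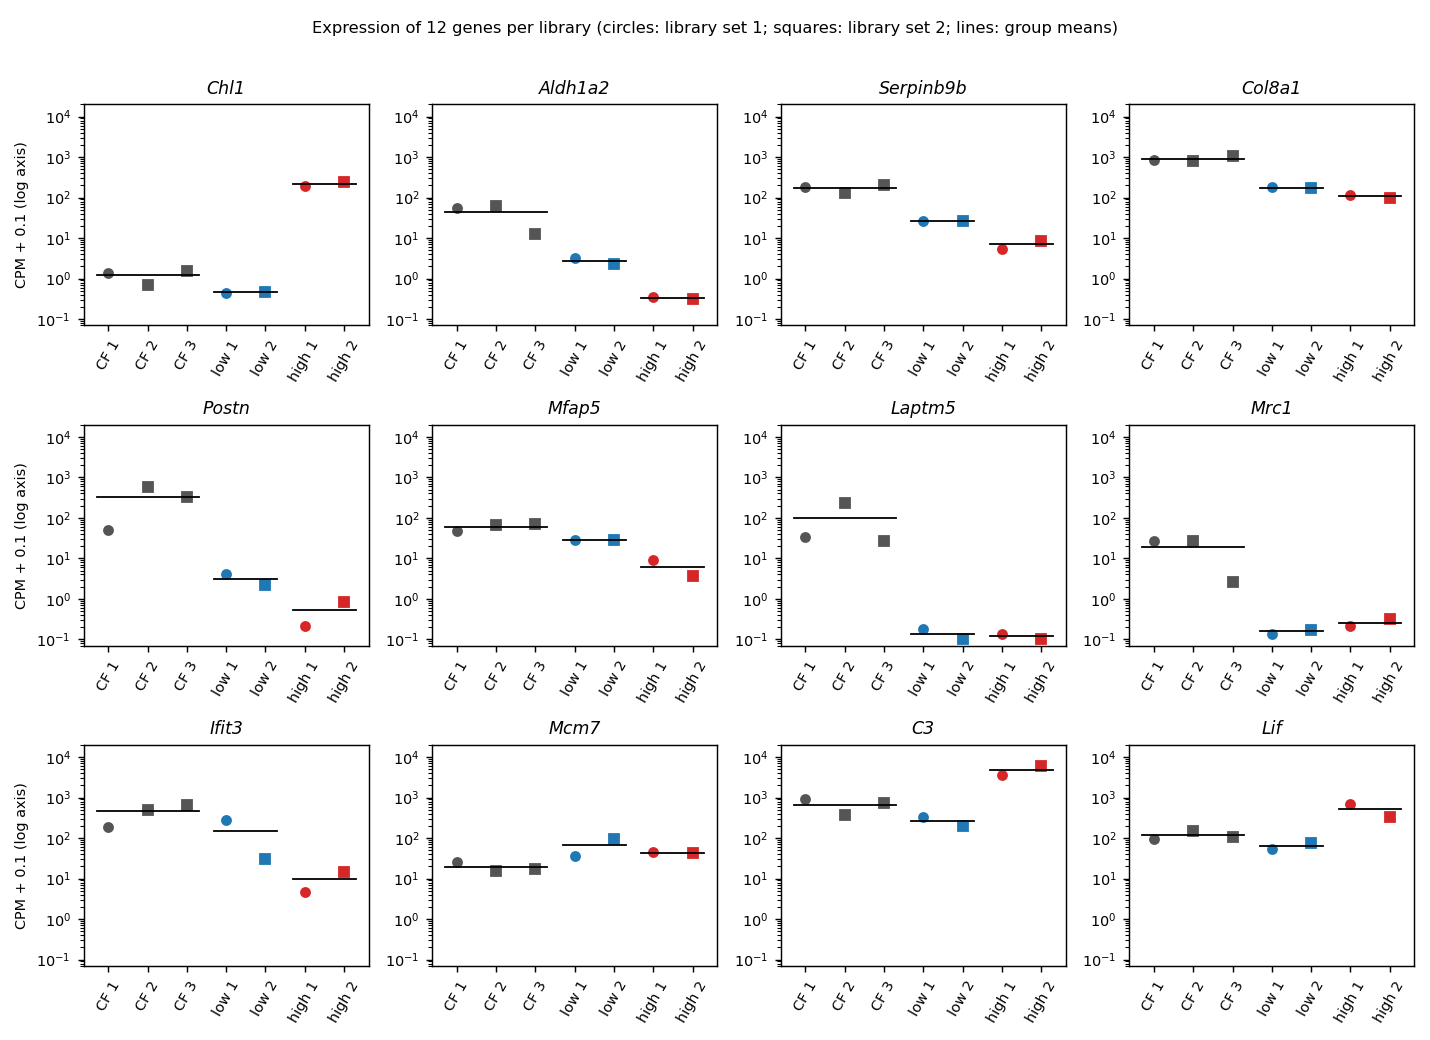
Expression of 12 genes in each library (vertical axis, CPM + 0.1 on a log axis), for CF in grey, low-passage iCPC in blue and high-passage iCPC in red, with circles for library set 1, squares for set 2 and lines for group means. Chl1 lies at 189 and 237 CPM in the high-passage libraries and at or below 1.43 CPM in the other libraries.

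Whole chromosomes stood apart in the iCPC libraries, a measure chosen after the data were seen. Median expression of the genes of a chromosome relative to CF stayed within 0.23 (log2) for every CF library and chromosome. In iCPC it lay outside this range in 29 of 80 cases of a library and a chromosome. The 338 genes of chromosome 12 had medians of -0.78 in low 1, -0.69 in low 2, -0.84 in high 1 and -0.67 in high 2. The 642 genes of chromosome 4 had medians of -0.67, -0.48, -0.82 and -0.34 in the same order. Chromosomes 6 and 18 had medians of 0.52 and 0.54 in low 1 and 0.52 and 0.55 in high 1, both of iCPC batch 1, against 0.06 and -0.50 in low 2 and 0.06 and -0.30 in high 2. Of the genes lower in iCPC at an unadjusted p under 0.05, 27.9% lay on chromosomes 4 and 12 (356 of 1277), of the higher genes 2.32% (11 of 475), and of all placed genes tested 9.68%. Both chromosomes were picked for their low medians in these same libraries, so these shares restate that choice and are no separate support. Eno1, Klf4, Laptm5, Isg15 and Cdc20, named above, lie on chromosome 4. Without the genes of both chromosomes, 9 lists were called in iCPC against CF, as with them.

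**Figure D3:**
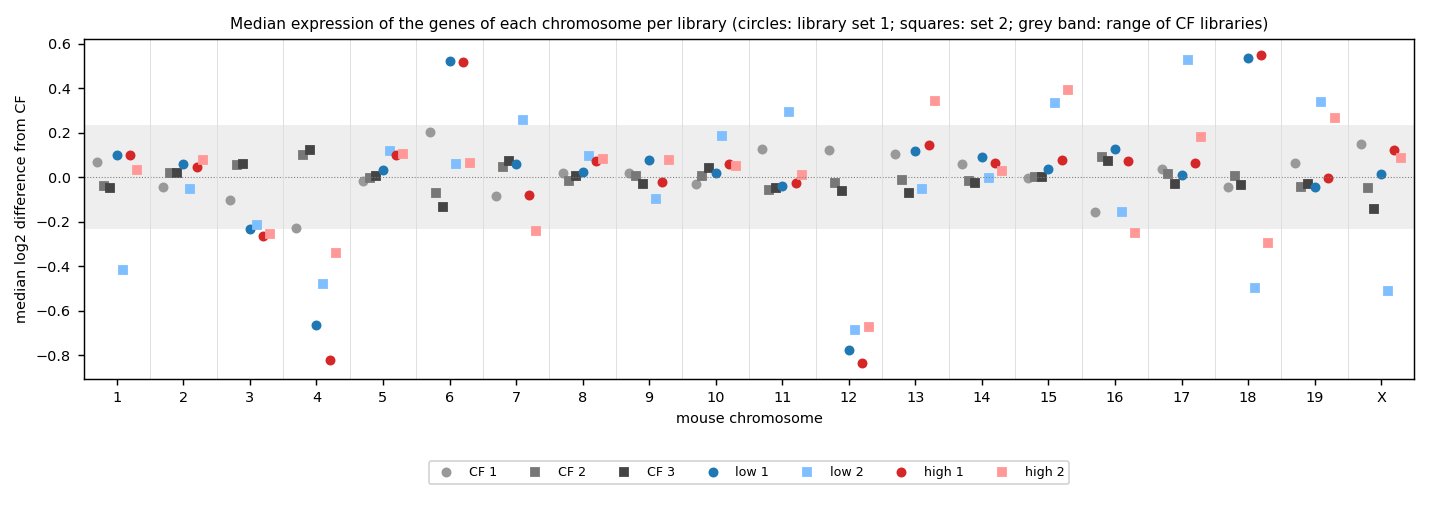
Median expression of the genes of each chromosome in each library relative to CF (vertical axis, log2), with mouse chromosomes on the horizontal axis. Circles are library set 1, squares set 2, and the grey band spans the CF libraries, which stay within 0.23, while all 4 iCPC libraries lie between -0.84 and -0.67 on chromosome 12.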

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

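The comparison of high with low passage tests whether the iCPC groups changed differently against CF, and each called result of it is given here. The tests of chance for iCPC against CF, those for the leukocyte and interferon lists and the regrouping by header were chosen after the results were seen. The 7 results are a log2 change of 9.19 for Chl1, and list medians of 0.74 for LIF/STAT3 targets, 0.41 for cholesterol synthesis, 1.40 for pluripotency, 1.45 for epithelium, -0.52 for oxidative phosphorylation and -0.63 for cell cycle. Chl1 was higher in both high-passage libraries than in each library labelled low passage. LIF/STAT3 targets, the pluripotency genes and the epithelial genes had medians of the same sign from low 1 to high 1 and from low 2 to high 2. For cholesterol synthesis, oxidative phosphorylation and cell cycle the signs were opposite. Low 2 and high 2 come from batches 4 and 3, so their difference also holds that between batches. These libraries also differed on the sex-linked genes, by a median of -4.84 from low 2 to high 2. The lists were picked by their pooled change, so agreement in sign is no separate support.

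Of 217 genes at least 4-fold apart between low 1 and both high-passage libraries, low 2 lay closer to low 1 for 29.5%, where the CF libraries gave 49.3% to 64.1%. The prediction written before for a high-passage culture was under 25%, and that for a low-passage culture over 50%, so whether its label or its header, passage 7, gives its passage cannot be told apart from these values. With low 2 grouped by its header, the cell cycle list turned (camera adjusted p = 9.01e-05, against 0.00301 in the other direction, over its 14 alternatives 6.25e-09 to 0.806). The low-passage group is then low 1 alone, assumed to vary like the other groups, and in the labelled groups the list was not called with an estimated correlation (adjusted p = 0.768), which was not run on the regrouped libraries. No biological explanation was tested for its position.

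For the lower leukocyte and interferon lists in iCPC, leukocytes in the CF cultures may account for the leukocyte list, since CF 2 exceeded CF 3 by a median of 3.89 on it and differed from CF 3 by at most 0.67 in size on any other tested list. CF 1 differed from CF 3 on more lists, by 2.97 for endothelium, -2.25 for pluripotency, 2.16 for epicardium, -2.02 for interferon and 1.74 for Hox genes against 1.55 for leukocytes. For the interferon list the difference of CF 2 from CF 3 was -0.23, so it did not follow the leukocyte list between these libraries. For either list this sets a single library against another, and the labels give CF 2 as female and CF 3 as male. It does not decide whether leukocytes were the source of the interferon result. A difference between the library sets as the whole source of the interferon result is argued against by the median of -2.73 within set 2, although set 1 showed -0.13. The change from fibroblast to iCPC, which the groups name, stays open for both lists.

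Other splits of the 7 libraries into 4 and 3 were fitted with iCPC as one group. The real split called 3 genes and the highest other split 2, so 1 of 35 splits, the real one, gave as many. This excludes chance only if libraries can be exchanged between the library sets, and by a margin of 1 gene. With 1 library of set 1 and 2 of set 2 kept in the smaller group there are 18 splits, too few for a share under 0.05, and the fit with 3 groups called 0 genes. Genes at an unadjusted p under 0.05 did not single out the real split (1609), since 3 other splits had more (2155, 1761 and 1610). For the gene lists 5 of 35 splits gave as many as the real 9, the highest other 10, and chance is not excluded for the number of lists. The cell cycle list had a camera adjusted p of 3.25e-10 in the real split. Some other splits gave smaller values, down to 1.46e-25 for CF 1, low 2 and high 1 against the rest, so this p does not single out iCPC against CF. For the leukocyte list the real split gave the smallest value, 6.30e-20, and CF 1, CF 2 and high 1 against the rest the next, 3.24e-14. The split that follows the library sets, with 1761 genes at an unadjusted p under 0.05, called 0 genes with edgeR and 3 lists.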

How the results depend on the processing

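The regrouping by header, each library set alone and the removal of chromosomes 4 and 12 were chosen after the data were seen. The alternatives moved the number of called genes more than directions. The cause of each difference below was not tested, except that fewer libraries or other genes enter some fits.

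Called genes for iCPC against CF, 0 with edgeR, were 36 with no filter, 774 with DESeq2, 3 on log2(TPM + 1), 15 on log2(TPM + 0.1), 5 with a library set block and 3 with both iCPC groups as one, and 0 to 72 with a library left out. For low passage against CF they were 426 with DESeq2 and 0 with a library left out. For high passage against CF, 3 with edgeR, they were 535 with DESeq2, 8 on log2(TPM + 1), 7 on log2(TPM + 0.1), 5 on log2(TPM + 1) with no filter, 10 with a library set block and 0 to 4 with a library left out. For high against low passage, 1 with edgeR, they were 2 with no filter or on log2(TPM + 1) with no filter, 70 with DESeq2, 0 with limma-voom, on log2(TPM + 0.1), with a library set block, with only the groups compared and with low 2 grouped by its header, and 0 to 2 with a library left out. A library left alone in its group is assumed to vary like the others.

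Replicate numbers do not establish pairs: the replicate 2 libraries of iCPC come from batches 4 and 3, and CF and iCPC of the same number shared deviations at r = 0.0971 to 0.136. Low and high of the same number shared them at r = 0.284, which also follows the library sets and, for replicate 1, batch 1. A replicate block gave 28, 0 and 0 called genes for iCPC against CF, high against CF and high against low, with adjusted p-values of 0.0786 for Chl1 and 0.0828 for Serpinb9b in high against CF and 0.139 for Chl1 in high against low.

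No list stayed called with an estimated correlation (0 lists) or with fry (0 lists) in any of the 4 comparisons. With a library left out, 2 to 9 lists were called between the passage groups. Set 1 alone turned Irf7 (0.17) and the interferon list (adjusted p = 0.883) in iCPC against CF. Low 2 grouped by its header turned, in high against low, Aurka (0.93), Ccnb2 (1.41), Cdc20 (1.71), Ndufb5 (0.34), Ndufb9 (0.32), Tpx2 (0.54) and Uqcrq (0.17) and the lists of oxidative phosphorylation (adjusted p = 0.0760) and cell cycle (9.01e-05). With a library left out, high against low ran from -2.80 to 0.0296 for Ccnb2, -2.69 to 0.22 for Cdc20 and -2.41 to 5.82 for Cdh1, and list adjusted p-values from 6.25e-09 to 0.615 for cell cycle, 2.48e-15 to 0.566 for cholesterol synthesis and 0.000138 to 0.949 for epithelium. Among single genes 3467 values kept direction and side of the threshold, 150 passed it newly, 33 lost it and 11 turned, and among lists 354 kept it, 99 lost it and 7 turned. Most of these single genes were not called in the main fit, so keeping the side mostly meant staying uncalled. Under 21 alternatives each, the call was kept in 17 for Chl1 and 11 for Serpinb9b in high against CF. For Chl1 in high against low it was kept in 11. On log2(TPM + 1) the median change of all genes was -0.16, 0.10 and 0.23 for low against CF, high against CF and high against low, against 0.02, 0.02 and -0.03 with edgeR. In low 2, the shallowest library, 3 counts correspond to 0.223 CPM and 7068 genes had 0 counts, and whether depth or the cells account for these was not tested.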

Other observations

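The chromosome pattern and the genes named here were chosen after the values were seen, and the tests on chromosomes 4 and 12, on cases with runs of opposite sign and on GC content in low 2 were written after their results. C3, Lif, Saa3 and Ccl2 were picked singly and stand for no tested group of genes. Each was higher in both high-passage libraries than in both libraries labelled low passage, and none was called over all genes (edgeR adjusted p = 0.840 for each). C3, a complement component, was at 331 and 201 CPM at low and 3617 and 6194 CPM at high passage, and Lif, a cytokine, at 54.0 and 74.8 and at 688 and 332 CPM. Saa3, an acute-phase protein, was at 13.9 and 105 CPM at low and 4372 and 1077 CPM at high passage, and Ccl2, a chemokine, at 12.7 and 49.4 and at 994 and 857 CPM. Tcf21 and Wt1, epicardial genes, followed the library sets among iCPC, which also separate iCPC batch 1 from batches 4 and 3. Tcf21 was at 0.584 and 2.98 CPM in low 1 and high 1 and at 271 and 274 CPM in low 2 and high 2, and Wt1 at 2.14 and 1.54 and at 32.7 and 60.5 CPM. Igf2, a growth factor, was at 1034 CPM in high 2 and 37.2 CPM in high 1.

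Y-linked genes differed within groups. Ddx3y was at 109, 0 and 69.1 CPM in CF 1, 2 and 3, 99.9 and 42.2 CPM in low 1 and 2, and 95.5 and 0.746 CPM in high 1 and 2. The labels give CF 2 as female and CF 3 as male, and no sex for the other libraries. Eif2s3y, Kdm5d and Uty were also at 0 counts in CF 2 and at 0.640, 0.426 and 0.213 CPM in high 2.

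A copy-number change is a candidate explanation for the lower chromosomes 4 and 12 in all 4 iCPC libraries. With each chromosome divided into 4 runs of genes in order, the highest median of any run of chromosome 4 or 12 in an iCPC library was -0.25, so each run was lower. Both chromosomes were picked for their low medians, and runs of a chromosome differed by up to 0.44 within a CF library, so this does not decide the question. A loss of 1 copy would give a log2 value of -1 if expression followed the copies, which no median of either chromosome reached. A gain of 1 copy would give 0.585, and chromosomes 6 and 18 came near it in low 1 (0.52 and 0.54) and high 1 (0.52 and 0.55). These libraries are of the same batch and the chromosomes were picked by their values, so this does not decide the question either. Over all chromosomes, 24 of the 29 cases outside the CF range had all 4 runs shifted the same way by at least 0.1. The prediction written before for a copy-number change asked for this in every case. It was not met, though too few cases failed to count against it. In 3 cases (chromosome 7 in low 2, chromosome 19 in low 2 and high 2) runs went opposite ways and differed by at least 0.69, against at most 0.44 in CF, which argues against a change along the whole chromosome there. Against CF of their own set 27 of 29 cases stayed outside the CF range, with medians of -0.88 to -0.39 on chromosomes 4 and 12. This argues against a difference between the library sets for these chromosomes. The CF range was not taken within a set, and set 1 has CF 1 alone as its reference, so the count for other chromosomes is less certain. GC content and transcript length are argued against outside low 2. After their trends were removed 24 of 29 cases stayed outside, with medians of -0.93 to -0.36 on chromosomes 4 and 12. In low 2 only 6 of 10 stayed outside, so GC content and transcript length stay open there. Both cases of low 2 with opposite runs fell into the range, chromosome 19 only narrowly (0.2096 against a limit of 0.2110). In high 2 chromosome 19 stayed outside at 0.254. RNA measures expression and not DNA, and regulation along whole chromosomes was not tested.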
